A study of Mus musculus with 8 samples.

How the data were processed

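Methylated DNA was measured in 8 mouse placentae on 2-colour Agilent CpG island arrays, 1 array per placenta, with no pooling. Per the labels, DNA pulled down with an antibody against 5-methylcytosine was labelled with Cy5 and input DNA with Cy3, and the placentae come from C57BL/6 mice at embryonic day 18.5. The groups (paternal TCDD, n = 5; control, n = 3) and replicate numbers were taken from the labels. Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1 and probe positions refer to mouse build mm9. The design has 94687 spots, of which 88737 are probes other than controls, 45 to 60 bases long.

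The deposited scanner files give each spot as an intensity, as raw mean and background signals and as a processed signal. Per the file headers, the processed intensity was background-subtracted, spatially detrended and dye-normalised with 1 linear factor per channel. The deposited scanner files also hold a log10 ratio of red over green, which was not used. The deposited value table of the series holds 88321 probes as log2 values. Set against each array's own processed ratio it had a slope of 0.999 to 1.00, so it is the log2 of Cy5 over Cy3, without centring. Its column medians were 0.037, 0.068, 0.060, 0.023 and 0.042 for paternal TCDD 1 to 5 and 0.043, 0.068 and 0.033 for controls 1 to 3. Scale, centring and direction of the table were thus settled.

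The values used here are log2 of the processed Cy5 over the processed Cy3 intensity, centred on the median of each array, with no loess or quantile step because many probes carry pull-down signal. Any change shared by most probes is lost in the centring. Control spots, 2223 probes marked as outliers on any array, and probes whose input signal was not well above background on all 8 arrays were left out, which kept 82788 probes, 82404 of them with a position. Median signals were 310.4 to 463 in the input channel and 405 to 575 in the pull-down channel. The ratio reports enrichment and not percent methylation, and it depends on CpG density and GC content. Single genes were not ranked by level, and differences between gene lists on an array are between different probes.

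Gene names came from the files (84308 probes named, 4429 not). A table of RefSeq names for GRCm38 was used for names only: it held 11206 of the names as symbols and 1279 as older symbols, which were updated, and 84 were kept as in the files. No mm9 gene models were used, so exons and introns are not given. Gene classes such as promoter or inside, which the planned comparison of annotation classes needed, were not in the columns used, so that comparison was made for chromosomes alone. A gene value is the mean over its probes, and probes of a gene can disagree. A region is a run of probes with gaps of at most 1000 bases and at least 3 probes.

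Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the only term, Benjamini-Hochberg at 0.05) per probe, region and gene. The 17 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Single measures were compared with exact two-sided permutation tests over the 56 splits of 8 arrays into 5 and 3. The named regions were by rule the 10 with a gene name in each direction that passed the threshold with the largest change. Places not filled went to the regions of lowest unadjusted p whose groups did not overlap. Pgr, Igf2 and the 2 genes of lowest p in each list were also named by rule. The main design, these rules and most alternatives were chosen before the data were examined.

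The scripts were tested on simulated data made from these arrays. Of regions shifted by 0.5 and by 1 among 13061, 30% and 79% were recovered with 0 false calls. Among 82788 probes the shares were 0% and 14%, and among 12515 genes 43% and 84%. Unshifted rows kept the group difference of a real row up to its sign, so false calls here do not measure an error rate. Camera at the preset correlation was run on simulated sets of 30 genes among 12515. It called 20 of 20 sets shifted by 0.2 with the right sign, and 0 of 20 unshifted sets. Camera with an estimated correlation was not run on them. The sets were random genes with shuffled values, so they lacked the correlation between genes of the real lists. That correlation was estimated at up to 0.49 (germline genes), so these counts do not carry over to the real lists.

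Alternatives were normexp background correction (offset 50) on the raw intensities, loess, quantile and scale normalisation, other filters on dim probes, the value table, the replicate number, slide and array position as terms, array weights, chromosome X left out, other region settings, a trended prior variance, and each array left out in turn. Leaving out both arrays of low contrast, loess on probe GC, the contrast and X dose of each array as covariates, and an estimated correlation in the alternatives where camera called a list were added after seeing the data. Slide is a batch: slides 2, 3 and 4 hold both groups, and within-slide values and fits with slide as a block were computed. Scan time follows slide. Array position is nearly the same split as group, since all controls lie at position 2.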

Results

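DNA methylation at CpG islands was measured in 8 placentae of C57BL/6 mice collected on embryonic day 18.5. TCDD (dioxin) is a persistent pollutant that acts through the aryl hydrocarbon receptor, a transcription factor that senses foreign compounds. Pregnant females received 10 µg/kg TCDD in corn oil, or the oil alone, by gavage late in pregnancy. Their sons were therefore exposed in the womb. As adults these sons, or control males, were mated to control females. Of the placentae, 5 were fathered by exposed males, the paternal TCDD group, and 3 by control males. Methylated DNA was pulled down with an antibody against 5-methylcytosine and hybridised in the Cy5 channel against input DNA of the same placenta in the Cy3 channel. A positive log2 ratio means more pull-down signal than at the median probe of the array. The 8 arrays lay on 4 slides. Slide 1 held paternal TCDD placentae 1 and 2, and slides 2, 3 and 4 each held 1 paternal TCDD placenta (3, 4 and 5) at position 1 and 1 control (1, 2 and 3) at position 2. All controls thus shared array position 2. Between 96.4% and 97.9% of the pull-down spots on an array lay well above background, and the number of arrays and the spread between them limit the precision.

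Placental DNA of both groups had higher ratios at germline than at housekeeping genes. Germline genes, whose promoters are methylated in somatic tissue, had a mean ratio of 0.36 ± 0.15 (SD, n = 5) in the paternal TCDD group and 0.36 ± 0.23 (SD, n = 3) in controls. Housekeeping genes, with unmethylated promoter islands, had -0.31 ± 0.13 (SD, n = 5) and -0.31 ± 0.087 (SD, n = 3). Germline genes lay above housekeeping genes on 8 of 8 arrays, by 0.25 to 0.94 (exact two-sided sign-flip test, p = 0.00781). This contrast lies between different probes and was not corrected for their CpG density or GC content. The size of this contrast varied strongly between placentae of the same group. It was 0.25 in paternal TCDD placenta 4 and 0.32 in control 3, against 0.65 to 0.94 in the other 6 placentae.

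These 2 arrays of low contrast, on slides 3 and 4, also had the narrowest ratios. Their interquartile ranges were 0.36 and 0.33, against 0.58 to 0.90 on the other arrays. The interquartile range was 0.60 ± 0.16 (SD, n = 5) after paternal TCDD and 0.63 ± 0.29 (SD, n = 3) in controls (exact permutation test, two-sided, p = 0.804). The germline contrast was 0.67 ± 0.26 (SD, n = 5) and 0.68 ± 0.31 (SD, n = 3; exact permutation p = 0.964). Probes with a ratio above 1 made up 1.71% ± 1.09 (SD, n = 5) and 1.99% ± 1.73 (SD, n = 3; exact permutation p = 0.786). All 3 measures had an adjusted exact p of 0.964. With 5 arrays against 3 the smallest exact p is 0.0179. The sign of each difference turned when certain single arrays were left out.

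**Figure D1:**
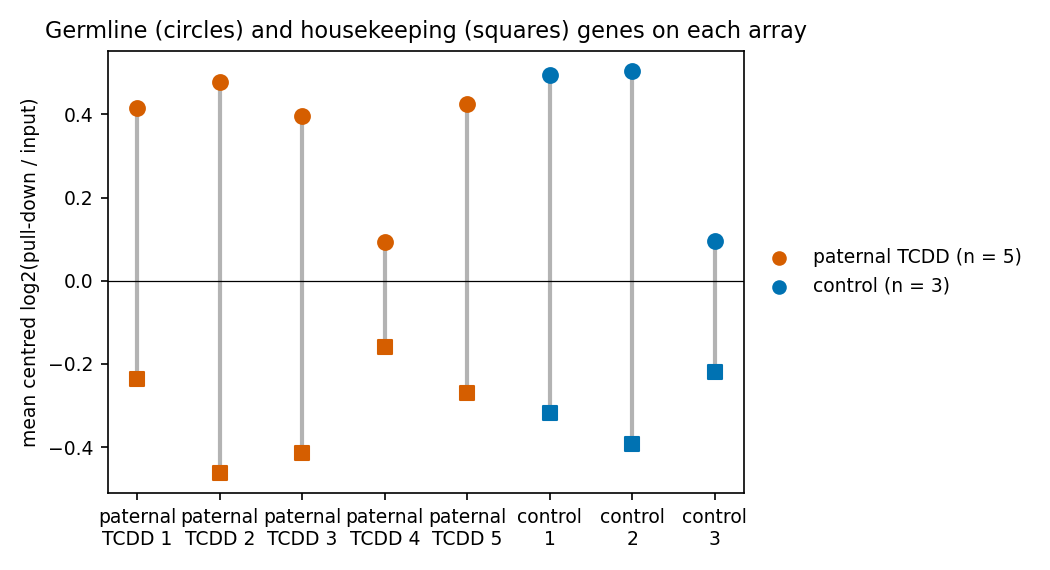
Mean centred log2 ratio of pull-down over input signal (vertical axis) of germline genes (circles) and housekeeping genes (squares) on each of the 8 arrays (horizontal axis), with orange for paternal TCDD (n = 5) and blue for control (n = 3). Circles lie above squares on 8 of 8 arrays, and the distance is 0.25 on paternal TCDD 4 and 0.32 on control 3.

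The study asked about 2 genes in particular, Pgr and Igf2. Pgr encodes the progesterone receptor, which keeps the uterus quiescent in pregnancy, and Igf2 encodes an imprinted growth factor of fetus and placenta. The ratio over the 8 probes of Pgr (mm9, chromosome 9, 8900444 to 8902039) was -0.17 ± 0.055 (SD, n = 5) in the paternal TCDD group and -0.19 ± 0.15 (SD, n = 3) in controls. The 16 probes of Igf2 (mm9, chromosome 7, 149844923 to 149850273) had -0.060 ± 0.070 (SD, n = 5) and -0.048 ± 0.12 (SD, n = 3). Pgr thus differed by 0.022 and Igf2 by -0.012, less than the spread between placentae.

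For Pgr the exact permutation test gave p = 0.768, and for Igf2 p = 0.875. In the limma fit over all genes both had an adjusted p of 1.00, with 95% intervals of ± 0.18 around the difference of Pgr and ± 0.17 around that of Igf2. These intervals are unadjusted and are not limits of detection. Of simulated genes shifted by 0.5, only 43% were called after adjustment over all genes, so such a call can miss differences well beyond these widths. That share concerns calls over all genes and not the precision of these 2 estimates. Within slides 2, 3 and 4, Pgr differed by 0.0012, 0.25 and -0.16 and Igf2 by -0.21, 0.18 and -0.040, and with slide as a block by 0.030 and -0.021. The probes of Igf2 were unlike one another. The probe at 149846759 to 149846803 had ratios from 0.38 to 1.57 and that at 149846243 to 149846296 from -1.16 to -0.0073. No probe of either gene passed the limma threshold, and the probe of Igf2 with the lowest unadjusted p (149846445 to 149846489) differed by -0.37. Without control 2, Pgr differed by -0.061, and without control 1, Igf2 differed by 0.045.

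**Figure D2:**
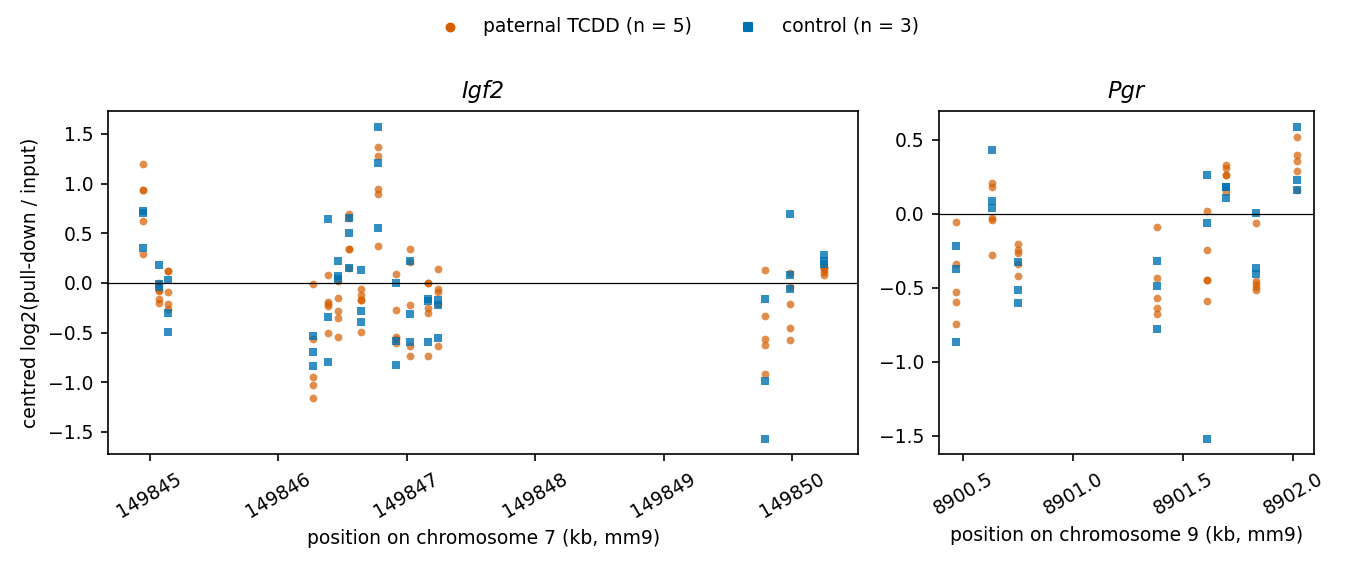
Centred log2 ratio of pull-down over input signal (vertical axis) of each probe of Igf2 and Pgr against its mm9 position in kilobases (horizontal axis), with orange circles for paternal TCDD placentae (n = 5) and blue squares for controls (n = 3). The points of both groups overlap along both genes, whose mean differences were -0.012 for Igf2 and 0.022 for Pgr.

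Across the CpG islands of the genome, no probe and no region separated the groups after adjustment. A region was a run of at least 3 probes with gaps of at most 1000 bases. The regions of lowest p are therefore given as values and not as changes. Among those higher after paternal TCDD in all 5 placentae than in all 3 controls, Exoc3l4 differed most, with 0.47 ± 0.21 (SD, n = 5) against -0.10 ± 0.13 (SD, n = 3). Slc7a14, of a family of cationic amino acid transporters, had 0.15 ± 0.13 (SD, n = 5) against -0.31 ± 0.10 (SD, n = 3). Among those lower, Aurkb, a kinase of chromosome segregation in mitosis, had -0.90 ± 0.18 (SD, n = 5) against -0.51 ± 0.095 (SD, n = 3).

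Limma called 0 of 82788 probes, 0 of 13061 regions and 0 of 12515 genes at an adjusted p of 0.05, and the lowest adjusted p of a region was 1.00. At an unadjusted p under 0.05, limma gave 1991 probes (2.40%), 186 regions (100 higher and 86 lower, 1.42%) and 196 genes (1.57%). The simulated data had such a p in 2.40% of unshifted probes, 1.43% of unshifted regions and 1.56% of unshifted genes. Unshifted rows there kept the group difference of a real row up to its sign. These shares therefore repeat the real ones and are no measure of chance. Over the other splits of the arrays into groups of these sizes, the median was 320 regions. By that count the nominal 5% is no measure of chance for regions in this fit. For probes and genes no such count was made. Shares below 5% therefore do not show fewer differences than chance. The groups did not overlap in 210 regions (1.61%) and 208 genes (1.66%), against 3.57% by chance. Region differences ran from -0.19 to 0.22 over the middle 95% of regions, and the median 95% interval of a region was its difference ± 0.24. In simulated regions with the spread of these arrays, 30% of those shifted by 0.5 and 79% of those shifted by 1 were recovered, with 0 false calls. With slide as a fixed block there were again 0 region calls and 63 regions at an unadjusted p under 0.05. Without both arrays of low contrast, an alternative chosen after seeing the data, limma called 0 regions and 662 (5.07%) had an unadjusted p under 0.05. The median interval was then ± 0.22, and simulated shifts were recovered in 35% and 86% of regions with 2 false calls. Neither count of false calls measures an error rate, since unshifted regions kept the real group differences up to sign.

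Of the 10 named regions higher in the paternal TCDD group, Exoc3l4, Slc7a14 and Cnmd differed most. Nphs1os, an antisense transcript of the nephrin locus (mm9, chromosome 7, 31250465 to 31250770, 3 probes), differed by 0.38 with a standard error of 0.074. Slc7a14 (chromosome 3, 31208342 to 31209022, 5 probes) differed by 0.46, but by 0.20 over probes above background in both channels and by 0.22 with normexp background correction. Exoc3l4 (chromosome 12, 112667716 to 112667989, 3 probes) differed by 0.58, and by 0.91 with array position as a covariate. Eefsec, the elongation factor for selenocysteine (chromosome 6, 88395992 to 88396713, 5 probes), differed by 0.30, and by 0.48 with slide block and array position. Cnmd, a cartilage protein that restrains vessel growth (chromosome 14, 80061030 to 80061465, 3 probes), differed by 0.45. The differences were 0.37 for Ankrd53 (0.11 with slide block and array position), 0.26 for Nhlh1, a neural transcription factor (0.40 with the same terms), 0.39 for Spout1, an RNA methyltransferase, and 0.23 for the potassium channel gene Kcnk4. Mid1, a ubiquitin ligase on microtubules (chromosome X, 166434962 to 166435845, 6 probes), had the tightest values, 0.15 ± 0.015 (SD, n = 5) against -0.045 ± 0.014 (SD, n = 3). Mid1 differed by 0.20, 0.19 and 0.19 within slides 2, 3 and 4, and the sign of such differences is fixed by the choice of regions whose groups do not overlap.

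Of the 10 named regions lower in the paternal TCDD group, Aurkb and Snrnp35 differed most. Dnajc17, a co-chaperone (mm9, chromosome 2, 119034232 to 119034844, 6 probes), differed by -0.30 with a standard error of 0.062. Snrnp35, a protein of the minor spliceosome (chromosome 5, 124933181 to 124933641, 3 probes), differed by -0.39. Aurkb (chromosome 11, 68853469 to 68853860, 5 probes) differed by -0.39 and Slc39a14, a transporter of zinc and manganese (chromosome 14, 70750798 to 70751251, 4 probes), by -0.28. The RNA-binding protein gene Nufip2 differed by -0.29, the mitochondrial ribosomal gene Mrpl45 by -0.27 and the actin-disassembly gene Wdr1 by -0.25. Josd1, a deubiquitinase, differed by -0.31, the oxysterol-binding protein gene Osbp by -0.26 and Sulf2, an enzyme that trims heparan sulphate, by -0.19. With normexp background correction Snrnp35 differed by -0.20, Mrpl45 by -0.14, Josd1 by -0.19 and Osbp by -0.15, and over probes above background in both channels Sulf2 differed by -0.11. Larger differences came with array position for Aurkb (-0.61) and Josd1 (-0.51) and without the filter on dim probes for Mrpl45 (-0.43), while with slide block and position Mrpl45 differed by -0.44 and Nufip2 by -0.18. All 20 named regions had a limma adjusted p of 1.00, with unadjusted values from 0.000724 upwards. The regions were picked for groups that do not overlap, so their tightness is not evidence of a difference.

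**Figure D3:**
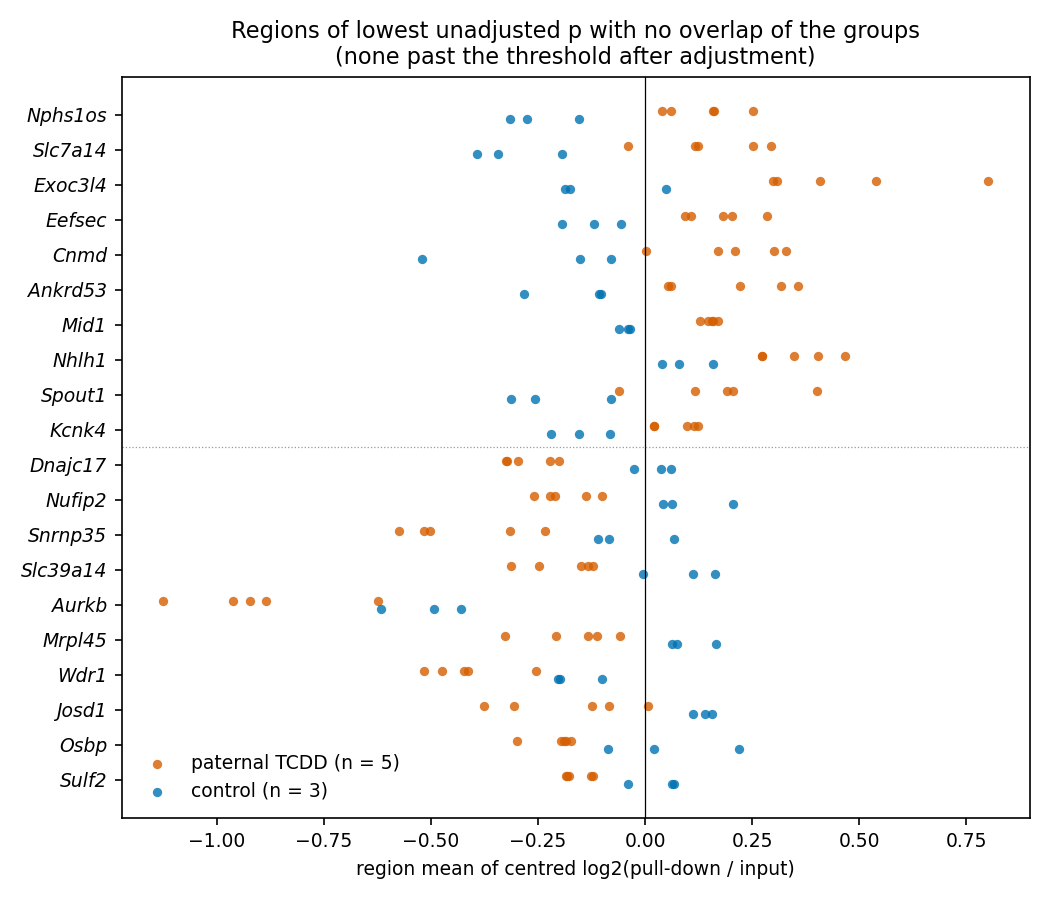
Mean centred log2 ratio of pull-down over input signal (horizontal axis) of the 20 named regions (vertical axis, by gene), with orange points for paternal TCDD placentae (n = 5) and blue points for controls (n = 3). The groups do not overlap in any of them because they were picked for that, and none passed the threshold after adjustment.

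Imprinted genes, which are expressed mainly from the copy of one parent, had similar mean ratios in both groups. A gene value averages all probes of a gene, so it is not a readout of methylation on one parental copy. Genes with a maternally methylated region (23 measured) had a mean of 0.13 ± 0.064 (SD, n = 5) after paternal TCDD and 0.14 ± 0.13 (SD, n = 3) in controls. Those with a paternally methylated region (4 measured) had 0.13 ± 0.067 (SD, n = 5) and 0.13 ± 0.17 (SD, n = 3). Other imprinted genes of placental clusters (16 measured) had -0.030 ± 0.025 (SD, n = 5) and -0.037 ± 0.031 (SD, n = 3). None of their members passed the limma threshold. Peg13, an imprinted non-coding RNA of 7 probes, had 0.39 ± 0.21 (SD, n = 5) against 0.70 ± 0.13 (SD, n = 3; exact permutation p = 0.0714). It differed by -0.44, -0.52 and 0.0039 within slides 2, 3 and 4. Slc22a3, an organic cation transporter, had 0.30 ± 0.039 (SD, n = 5) against 0.17 ± 0.068 (SD, n = 3), and its exact permutation p of 0.0179 is the smallest possible. As Slc22a3 was named for its low p on these same arrays, its exact p is no added evidence. The difference of Slc22a3 was 0.13, and 0.074 with normexp background correction. Blcap differed by 0.14 (-0.050 with slide block and array position) and Jade1 by -0.10 (-0.049 without control 2). Rasgrf1 differed by 0.083, but by -0.25, 0.53 and -0.11 within slides 2, 3 and 4 and by -0.095 without control 2. Dlk1 differed by -0.043, by -0.12, -0.48 and 0.22 within the slides and by 0.036 without paternal TCDD 4, and it also turned without control 2.

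Genes that build and serve the placenta also gave overlapping levels. Trophoblast regulators (38 measured) had -0.094 ± 0.032 (SD, n = 5) after paternal TCDD and -0.097 ± 0.011 (SD, n = 3) in controls, and placental transport genes (30 measured) -0.20 ± 0.083 (SD, n = 5) and -0.18 ± 0.079 (SD, n = 3). Among their members, Nodal differed by 0.13, Eomes, a T-box factor of trophoblast stem cells, by 0.086, the taurine transporter gene Slc6a6 by -0.18 and the fatty acid transporter gene Slc27a1 by 0.11. With array position in the fit Nodal turned to -0.018 and Slc6a6 to 0.0086, and with slide block as well Eomes turned to -0.030 and Slc27a1 to -0.020. Without control 2 Slc6a6 differed by -0.11, and without control 3 Slc27a1 differed by 0.057. Growth factor and vascular signalling genes (35 measured) had -0.096 ± 0.041 (SD, n = 5) and -0.065 ± 0.026 (SD, n = 3). Their lowest unadjusted p belonged to Tsc1, a brake on mTOR (difference -0.22), and to Hif1a, the hypoxia factor (-0.11). Over probes above background in both channels Tsc1 differed by -0.0045, without paternal TCDD 2 by -0.12, and with normexp background correction Hif1a differed by -0.036.

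Genes of the pathways that TCDD and progesterone act through had list means that overlapped between the groups, while Nr5a1 did not overlap. The aryl hydrocarbon receptor pathway (29 measured) had -0.12 ± 0.038 (SD, n = 5) after paternal TCDD and -0.11 ± 0.026 (SD, n = 3) in controls. Aldh1a3, a retinoic acid synthase, differed by 0.11. Steroid hormone signalling genes (27 measured) had -0.073 ± 0.025 (SD, n = 5) and -0.095 ± 0.0035 (SD, n = 3). In that list Nr5a1, the steroidogenic factor, had 0.066 ± 0.078 (SD, n = 5) against -0.088 ± 0.087 (SD, n = 3; exact permutation p = 0.0179, the smallest possible). Nr5a1 was named for its low p on these same arrays and did not pass the limma threshold, so its exact p is no added evidence. The estrogen receptor gene Esr2 differed by 0.13 on 1 probe. Esr2 differed by -0.055, -0.093 and 0.35 within slides 2, 3 and 4, by 0.059 with normexp background correction, by 0.23 without control 1 and by 0.046 without control 3. Inflammation and parturition genes (30 measured) had -0.0044 ± 0.0091 (SD, n = 5) and -0.033 ± 0.071 (SD, n = 3), where the chemokine gene Cxcl12 differed by 0.16 and Socs1 by -0.084. Cxcl12 differed by 0.11, 0.37 and 0.010 within slides 2, 3 and 4 and by 0.042 without control 2, and Socs1 by -0.050 without control 3.

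The genes that write and read DNA methylation had the lowest unadjusted p of any list in camera, but not in the other tests. Their adjusted camera p of 0.639, shared with other lists, is not past the threshold. In fry and the exact permutation test, steroid hormone signalling genes had the lowest p (unadjusted, 0.150 and 0.161). The list of DNA methylation and chromatin machinery (41 measured) had -0.16 ± 0.069 (SD, n = 5) after paternal TCDD and -0.13 ± 0.091 (SD, n = 3) in controls. It differed by -0.027, but by 0.023 without control 3. Eed, a subunit of Polycomb complex PRC2, differed by -0.16 and the insulator protein gene Ctcf, whose groups did not overlap, by -0.13 (exact permutation p = 0.0357; -0.086 with normexp background correction). Both were named for their low p on these same arrays and did not pass the limma threshold. Hox genes (39 measured) had 0.062 ± 0.065 (SD, n = 5) and 0.077 ± 0.14 (SD, n = 3), with Hoxd8 at a difference of -0.21 (-0.13 without paternal TCDD 4) and Hoxd9 at -0.11 (-0.057 with normexp and -0.076 without paternal TCDD 3). Other developmental transcription factors (65 measured) had -0.012 ± 0.025 (SD, n = 5) and -0.024 ± 0.13 (SD, n = 3), with Isl1 at -0.18 (-0.12 without control 3) and Pax6 at 0.14 (0.27 without control 1 and 0.050 without control 2). In the germline list Dpep3 differed by 0.17, but by 0.12, -0.49 and 0.73 within slides 2, 3 and 4 and by -0.016 without control 3. Spo11 differed by 0.084 and by -0.13, -0.062 and 0.27 within the slides, by 0.14 without control 1 and by 0.00040 without control 3. Among housekeeping genes Hmbs differed by -0.16 and Vps29 by -0.14, or by -0.074 and -0.063 without control 2.

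Markers of other cell types of a placenta also had list means that overlapped between the groups, while the single gene Spi1 did not overlap. Endothelium and fetal mesenchyme markers (11 measured) had 0.0071 ± 0.013 (SD, n = 5) after paternal TCDD and -0.030 ± 0.13 (SD, n = 3) in controls, with Sox18 at a difference of 0.19. Kdr differed by 0.091, but by -0.029, 0.36 and -0.13 within slides 2, 3 and 4 and by -0.016 without control 2. Blood and immune cell markers (11 measured) had 0.10 ± 0.033 (SD, n = 5) and 0.075 ± 0.038 (SD, n = 3). Among them Spi1, a master factor of myeloid cells, had 0.21 ± 0.19 (SD, n = 5) against -0.094 ± 0.094 (SD, n = 3; exact permutation p = 0.0357). Spi1 was named for its low p on these same arrays and did not pass the limma threshold. Its value was 0.55 in paternal TCDD 2, against 0.071 to 0.16 in the rest of that group. Lyl1 differed by -0.11, or by -0.0069 over probes above background in both channels, -0.011 without control 1 and -0.25 without control 3. Decidua markers (12 measured) had -0.0032 ± 0.034 (SD, n = 5) and -0.011 ± 0.11 (SD, n = 3), with Foxo1 at 0.066 (-0.032 with slide block and array position) and Hand2 at -0.089 (-0.19 without control 3 and -0.037 without control 2).

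Camera in limma called 0 of the 17 lists, with an adjusted p of 0.639 or more, of 0.963 with an estimated correlation and of 0.987 in fry. No member of any list was called over all genes or adjusted over the list alone, and only Peg13 and Spi1 had an unadjusted limma p under 0.05. Of the 35 named genes 16 had the sign of their pooled difference within all of slides 2, 3 and 4. For germline, housekeeping and paternally methylated imprinted genes the mean, the median and the direction of the camera test differed in sign, at mean differences of -0.0034, 0.0026 and 0.00010. With slide as a block 0 lists were called, and the germline list differed by -0.099, -0.41 and 0.33 within slides 2, 3 and 4. Camera called 5 lists without control 1, 3 lists without control 3 and 1 list, the germline genes at -0.071, without both arrays of low contrast. With an estimated correlation these fits called 0 lists, at adjusted p of 0.220, 0.950 and 0.925 or more. That mode was not run on simulated sets, so how often it keeps a true shift is unknown and its 0 calls do not exclude one.

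**Figure D4:**
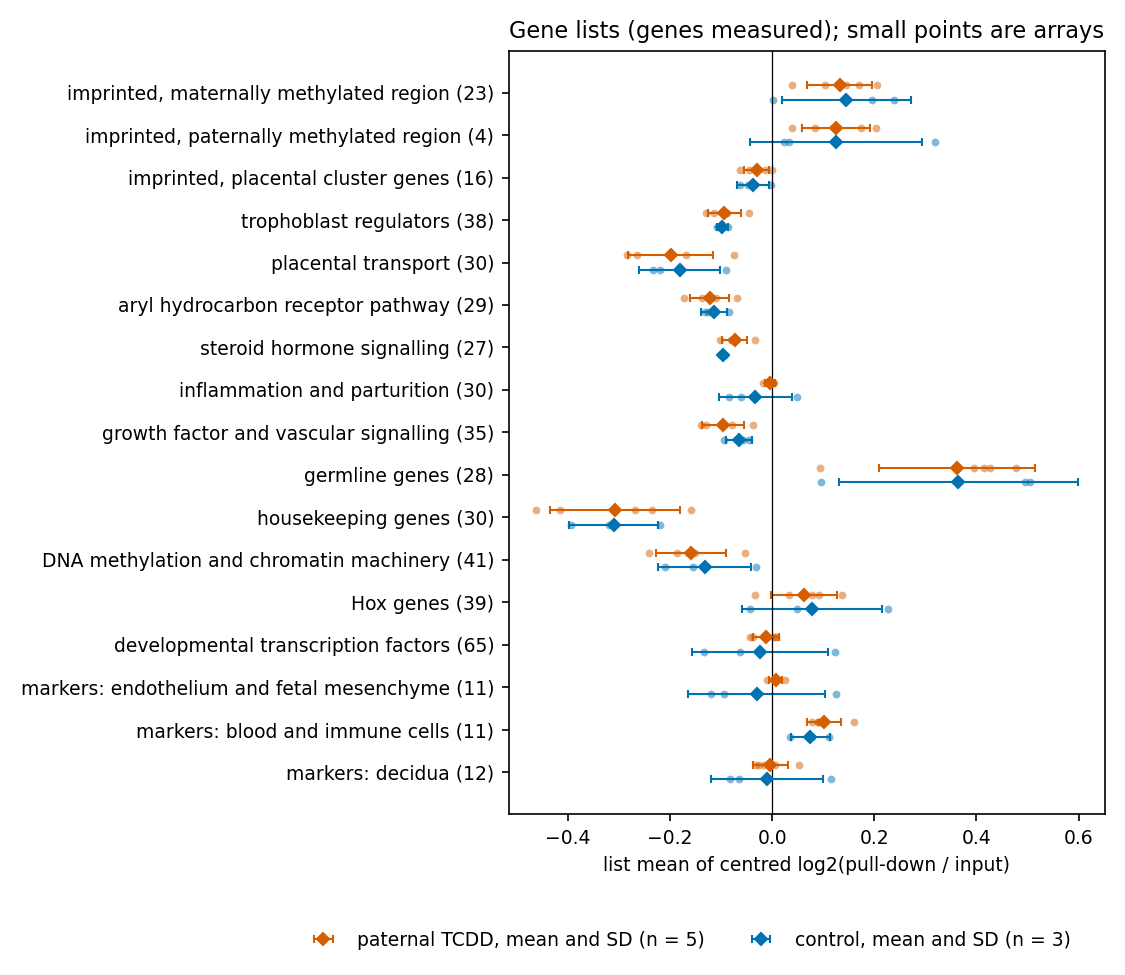
List mean of the centred log2 ratio of pull-down over input signal (horizontal axis) for the 17 gene lists (vertical axis, genes measured in brackets), with diamonds and bars for mean and SD, small points for arrays, orange for paternal TCDD (n = 5) and blue for control (n = 3). The groups overlap in every list, from housekeeping genes at -0.31 to germline genes at 0.36.

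Whole chromosomes were at the same level in both groups within error. Of 20 chromosomes tested, all had an adjusted exact permutation p of 0.929. Chromosome X had a mean ratio of 0.0026 ± 0.10 (SD, n = 5) after paternal TCDD and 0.043 ± 0.14 (SD, n = 3) in controls, a difference of -0.040 (exact permutation p = 0.679) that was -0.057, -0.19 and 0.18 within slides 2, 3 and 4. Without control 2 it was 0.039. Fetal sex is not in the labels, and the array carries no probe on chromosome Y. The median input signal of X probes relative to autosomes was -0.15, -0.13, -0.17, 0.074 and 0.046 in paternal TCDD placentae 1 to 5 and -0.18, 0.067 and 0.063 in controls 1 to 3, so it was not equal among the placentae of either group. It lay below autosomes on all arrays of slides 1 and 2 and above them on all arrays of slides 3 and 4.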

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

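All tests of explanations in this part were chosen after the result was seen, while the rule of the search for placentae far from the rest of their group was fixed before the data were examined. The 4 measures of single arrays that it covered besides the compared results were picked afterwards. It covered 99 results in the paternal TCDD group of 5 and found 8, where chance alone finds about 5 in 100, and the control group of 3 is too small for it.

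Paternal TCDD 4 stood apart in 3 of the 8. Its germline genes had a mean ratio of 0.094, against 0.40 to 0.48 in the other 4 placentae of the group. Across regions, which are not independent replicates, its median correlation with the 7 other arrays was r = 0.330, against 0.878 to 0.893 for the rest of the group. Its Osbp region had -0.30, against -0.20 to -0.17. The other flagged values were those of paternal TCDD 2 for blood and immune cell markers (0.16, against 0.079 to 0.091), Spi1 (0.55, against 0.071 to 0.16) and Nr5a1 (0.20, against 0.015 to 0.053), of paternal TCDD 1 for Slc22a3 (0.37, against 0.27 to 0.29) and of paternal TCDD 5 for Kdr (-0.24, against -0.033 to 0.0050).

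Control 3 resembled paternal TCDD 4: both arrays had narrow ratios, while their input signals correlated with those of other arrays as usual (median r of 0.976 and 0.981). They differed in how their ratios followed the probes. The r with probe GC was 0.41 on control 3, within the 0.29 to 0.46 of the wide arrays, but 0.082 on paternal TCDD 4. With the CpG count of the probe it was 0.23, within their 0.19 to 0.34, and -0.062. Dim spots do not account for the narrow ratios. The lower share of pull-down spots well above background on these 2 arrays was 97.5%, above that of 3 of the wide arrays. Their median correlations with the other arrays argue against a constant scaling of the ratios. The higher of them, 0.514, lay below the 0.845 or more of the rest. The 1 control among the 2 arrays argues against the paternal exposure as a cause shared by both. For paternal TCDD 4 alone the exposure was not tested. Little enrichment in the pull-down stays open: the regions' slopes on the mean of the 6 arrays of wide ratios were above 0, at 0.14 and 0.231, but narrow ratios alone keep such slopes small, so they decide nothing. Little enrichment and lower methylation at these loci in both placentae cannot be told apart.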

How the results depend on the processing

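Alternatives with array position or single arrays left out were planned; those with both low-contrast arrays left out, GC loess, contrast or X dose as covariates, and an estimated correlation where lists were called, were chosen after seeing the data. Limma called 0 probes and 0 regions under every alternative run, while regions at an unadjusted p under 0.05 went from 21 (slide block with array position) to 718 (contrast covariate), against 186. The number of each replicate does not pair the samples (r of deviations 0.23, 0.60 and -0.42 for equal numbers). With it as a replicate block there were 0 region and 0 probe calls, 361 regions at an unadjusted p under 0.05, 0 lists, and Dlk1 turned to 0.040. Not run were promoter-annotated probes and annotation classes, which need probe classes. Of pull-down spots 96.4% or more were well above background, yet the dim ones bore on single values: over probes above background in both channels Tsc1 went from -0.22 to -0.0045, Lyl1 from -0.11 to -0.0069 and Slc7a14 from 0.46 to 0.20.

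None of the 20 named regions changed direction under any alternative, but normexp moved 5 of them by over 1.5 times, array position 4, slide block with position 7, the filter on both channels 2, no filter 1 and a gap of 500 bases 1. The regions were picked for groups that do not overlap, so with arrays left out their direction was fixed in advance. Of the 35 named genes array position moved 24 by over 1.5 times, slide block with position 24, array weights 14, normexp 12, both low-contrast arrays left out 9 and the replicate block 8, and other alternatives 6 or fewer. The cause was not tested for the turns that follow. Igf2 turned to 0.032 with normexp, and Pgr to -0.0090 with quantile normalisation and -0.0057 with scaling. With array position as a covariate, Pgr was -0.041, Igf2 0.054, Dlk1 0.12, Nodal -0.018 and Slc6a6 0.0086, and 1 list was called (germline, 0.11), but 0 with an estimated correlation (adjusted p = 0.517 or more). With slide block and position, Pgr was -0.070, Igf2 0.084, Blcap -0.050, Rasgrf1 -0.031, Eomes -0.030, Slc6a6 0.012, Slc27a1 -0.020 and Foxo1 -0.032. With array weights Rasgrf1 was -0.019 and 2 lists were called (Hox genes, -0.079, and developmental transcription factors, -0.050), but 0 with an estimated correlation (adjusted p = 0.981 or more). With slide as a random block Dlk1 was 0.017, and without both low-contrast arrays 1 list was called, and 0 with an estimated correlation (adjusted p = 0.925 or more). Mean differences of 14 of the 17 lists changed sign under some alternative, none beyond 0.20.

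Leaving out each array in turn gave Pgr -0.061 to 0.084, Igf2 -0.071 to 0.045, Dlk1 -0.14 to 0.036, Rasgrf1 -0.095 to 0.21, Kdr -0.016 to 0.18 and Dpep3 -0.016 to 0.30. Some left-out array moved 22 of the 35 named genes and 0 of the 20 named regions by over 1.5 times. As the regions were picked for groups that do not overlap, their 0 is not evidence of robustness. The interquartile range differed by -0.18 to 0.10, the germline contrast by -0.19 to 0.11, probes above 1 by -1.26 to 0.385 percentage points and chromosome X by -0.091 to 0.039. Between 0 and 5 lists were called. With an estimated correlation 0 were called in each of these fits (adjusted p = 0.220 or more).

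Chance cannot be excluded for the 186 regions at an unadjusted p under 0.05, since 39 of the 56 splits of the arrays into 5 and 3 gave as many or more, up to 4713. For probe, region and list calls the real counts were 0, which all 56 splits reach by construction, so the splits decide nothing there. The highest other split called 2284 probes and 1996 regions, and it set paternal TCDD 1 and 4 with control 3 apart. Both low-contrast arrays lay on the same side in 26 of the 56 splits, but only this 1 split called any probe or region. The reason for its calls was not tested. Up to 8 lists were called by another split, and 46 of the 56 splits called some list.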

Other observations

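The tests of list shifts split by left-out control, of slide for the X input and of drift in the X ratio, the estimated correlation in fits that leave out an array, and the genes of the next paragraph, were chosen after the results were seen. The tests of unequal spread over all left-out arrays and of drift in the input signal were fixed before theirs.

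Several germline and imprinted genes carried positive ratios in both groups, and none of those named here passed the limma threshold between them. Mov10l1, a helicase of the piRNA pathway, had 0.85 ± 0.24 (SD, n = 5) after paternal TCDD and 0.72 ± 0.51 (SD, n = 3) in controls. Slc25a31, a nucleotide carrier of testis mitochondria, had 0.79 ± 0.35 (SD, n = 5) and 0.73 ± 0.29 (SD, n = 3), and Sycp3, of the meiotic chromosome axis, 0.54 ± 0.11 (SD, n = 5) and 0.58 ± 0.21 (SD, n = 3). Dazl, an RNA-binding protein of germ cells, had 0.35 ± 0.19 (SD, n = 5) and 0.37 ± 0.21 (SD, n = 3). Among imprinted genes, Zim3 had 1.02 ± 0.24 (SD, n = 5) and 1.01 ± 0.33 (SD, n = 3), and the non-coding RNA gene Kcnq1ot1 0.37 ± 0.16 (SD, n = 5) and 0.30 ± 0.30 (SD, n = 3). Peg3 lay near the array median, at 0.017 ± 0.039 (SD, n = 5) and 0.016 ± 0.047 (SD, n = 3). Peg10 lay below it, at -0.39 ± 0.16 (SD, n = 5) and -0.29 ± 0.15 (SD, n = 3).

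Gene list shifts appeared when certain single controls were left out. With an estimated correlation 0 of them were called, and at the preset correlation 46 of the 56 splits of the arrays called some list. Without control 1, camera in limma called 5 lists, all higher after paternal TCDD: developmental transcription factors (0.085, adjusted p = 1.92e-07), Hox genes (0.059), endothelium markers (0.11), decidua markers (0.071) and inflammation genes (0.068), each with an adjusted p of 0.220 or more with an estimated correlation. Without control 3 it called 3 lists, all lower: germline genes (-0.14 ± 0.11 (SE), adjusted p = 0.000738), maternally methylated imprinted genes (-0.084 ± 0.049) and Hox genes (-0.076 ± 0.068), each with an adjusted p of 0.950 with an estimated correlation. Without control 1 the estimated correlation of inflammation genes (-0.024) and endothelium markers (-0.043) lay below the preset 0.01, yet these calls were lost. Such a loss therefore need not come from correlation between genes. Camera with an estimated correlation was not run on simulated sets, so how often it keeps a true shift is unknown. With the interquartile range of each array as a covariate 4 of the 8 calls at the preset correlation were left, all without control 1. Another 4 were lost and 3 others appeared. Without control 1 the groups differed in interquartile range, over probes outside the lists, by only -0.015. There was thus little unequal spread behind those calls and little for the covariate to remove. Without control 3 the covariate gave germline genes -0.0092 ± 0.081 (SE), the imprinted genes -0.063 ± 0.061 and Hox genes -0.054 ± 0.086, errors too wide to say whether unequal spread lay behind these calls.

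The input signal of chromosome X lay below that of autosomes on the 4 arrays of slides 1 and 2 and above it on the 4 arrays of slides 3 and 4, over a range of 0.25, while no autosome ranged over more than 0.0510, which argues against a drift that autosomes share. As 0 of the 4 slides held both levels, a difference in fetal sex and a fault of slide confined to X cannot be told apart. The mean X ratio ranged over 0.32 and was highest in paternal TCDD 5 (0.17) and control 2 (0.20), which both had X input above autosomes, while no autosome ranged over more than 0.159. Paternal TCDD 4 and control 3 had X input above autosomes too (0.074 and 0.063), but X ratios of 0.0070 and -0.015 on arrays of low contrast. Fetal sex, with methylated islands on the inactive X of females, may lie behind both patterns, but it is not in the labels and its relation to the X ratio was not tested, so it stays open for both groups.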
